A study of Mus musculus with 6 samples.

How the data were processed

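Small RNA was sequenced from extracellular vesicles, described in the labels as exosomes (small membrane vesicles that cells release), collected from the muscle of young and of old mice. The series holds 6 libraries, 3 of young and 3 of old muscle, and the group and replicate number of each library were taken from its title. The labels do not say whether the replicates came from separate animals, so that p-values measure only the spread between these libraries, which may be technical. The ages of the mice, their sex, the muscles used and the vesicle isolation are not given in the sources used here.

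The deposited table held raw counts of reads per mature miRNA locus, written by featureCounts version 2.0.6, per the file headers. The authors aligned reads with BWA to the mouse build mm10, per the submitters' processing notes; the BWA version, its settings and the adapter trimming are not given in the sources used here. Per the file headers, the authors counted reads over mature miRNA features of a miRNA annotation file, with no strand option, no option for reads that overlap more than 1 feature and no option for multi-mapping reads. A read over 2 overlapping features is left unassigned by that command, and a read counts for a locus on either strand. The consequences are visible in the table. Of its 2110 loci, 106 overlapped another locus on the opposite strand, by 11 to 22 bases, and 104 of them held 0 counts in all libraries. Of 22 mature identifiers with at least 2 copies outside an overlap, 1 or more of them above 100 counts on average, 15 had copies within 1.1-fold of each other. The copies of miR-128-3p were 1.42-fold and those of miR-92a-3p 38.7-fold apart. A count at 1 of 2 even copies need not reflect the activity of that locus.

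The table identifies each locus by a mature miRNA identifier and its coordinates and carries no names. Names were assigned by position, from the miRNA genes of GENCODE release M21 on GRCm38, the assembly also called mm10. The locus had to lie inside a miRNA gene on the same strand with a tolerance of 3 bases, older names came from the RefSeq synonyms, and the arm (5p or 3p) came from the position in the hairpin. In this way 2024 loci received a miRNA symbol and 86 did not, and the latter held 0.0018% of all counts. The 2110 loci carried 1966 mature identifiers, of which 82 stood at more than 1 locus. Host genes were read from the same annotation, as the gene whose exon or intron holds the locus.

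Differences between old and young were tested with edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) on the counts as deposited, after filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15) and TMM scaling. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 347 loci tested, with a threshold of 0.05. These 347 loci stood for 310 mature miRNAs and held 99.92% of all counts. Values per library are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries. They are relative to the other counted miRNAs and do not give an amount per vesicle or per mass of muscle. A standard error beside a log2 fold change was derived from the unshrunken coefficient and its F statistic.

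Before the data were examined, 19 lists of miRNAs were fixed: miRNAs enriched in muscle, marker miRNAs of red blood cells, leukocytes, endothelium, smooth muscle and fibroblasts, liver, epithelium and neural tissue, 9 families or genomic clusters, miRNAs named in work on senescence and inflammation, and miRNA entries that may be fragments of rRNA or tRNA. A list was tested when at least 3 of its loci passed the filter, which 17 did, with camera in limma version 3.58.1 at a preset correlation of 0.01, and its p was adjusted over these 17 lists. Camera with an estimated correlation and fry, which asks whether a list's members move on balance in 1 direction, were run beside it. Shares of counts and library composition were compared by two-sided exact permutation tests, whose smallest possible p for 3 against 3 libraries is 0.1, so that no such test could pass 0.05.

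The miRNAs named in the report followed a rule set at the same time: among loci past the threshold whose groups did not overlap, up to 10 higher and 10 lower by p; the 10 most abundant loci; and from each list the 2 most abundant loci plus up to 4 past the threshold. Any other miRNA was chosen after its values were seen, also where the text does not repeat it. Among these are miR-133b-3p, miR-34a-5p, let-7i-5p, let-7g-5p and miR-30c-5p.

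The procedure was tested on simulated counts for old against young with 3 libraries each, with 200 loci changed. Counts were drawn from the real means, library totals and common dispersion (0.0392). Over 341 tested loci, the test recovered 10 of 24 loci changed 1.5-fold, 12 of 18 changed 2-fold and all 25 changed 4-fold, and called 2 unchanged loci. With nothing changed no list was called, and with the muscle-enriched list raised 2-fold that list alone was called. Each locus was drawn independently, so that the simulation could not show false list calls from members that vary together. All loci had the same dispersion and no library was made to stand apart, so that recovery in the real data may differ. In the real data the estimated correlation of the muscle-enriched list was 0.313.

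Library totals ran from 904892 to 1706396 counts. A locus at 0 could hold up to 3 counts, or 1.76 to 3.32 CPM depending on the library. Exact binomial (Clopper-Pearson) intervals at 95% were computed for the share of the most abundant miRNA. Reads carried no molecular identifiers in the table, so that intervals and limits cover counting error only. Alternatives covered the scaling (RLE, upper quartile, library totals), the low-count filter (none, or at least 50 counts in every library of 1 group), DESeq2 version 1.42.0, limma-voom, the replicate number as a block, removal of the 5 most abundant loci, and each library left out in turn. Summing identical copies and removing the possible rRNA or tRNA entries were chosen after seeing the data.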

Results

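The data were counts of mature miRNAs in vesicles from muscle of young and old mice, 3 libraries in each group. Young replicates 1, 2 and 3 held 1459826, 1706396 and 1523331 counts, and old replicates 1, 2 and 3 held 904892, 1417733 and 1383960. A count was present at 687, 701 and 699 loci in the young libraries and at 618, 683 and 655 loci in the old ones. Mean totals were 1563180 ± 128025 in young and 1235530 ± 286837 in old (SD, n = 3 each), and neither the totals nor the number of loci with a count could pass a threshold of 0.05 in an exact permutation test (p = 0.1 for both, the smallest possible). The 3 young libraries differed from each other by 16.9 to 34.0 chi-square units per degree of freedom, so that no pair agreed within sampling noise.

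Shares and ranks given here cover only the loci that could be counted. Of 106 overlapping loci, 104 held 0 counts, among them miR-24-3p, miR-126a-3p and miR-486a-5p. The counted vesicle miRNA pool was dominated by miR-21a-5p, which lies in an exon of Vmp1 in the annotation (chromosome 11, 86584120 to 86584141, mm10). It took 51.0% ± 1.29 of the counts in young and 45.8% ± 9.17 in old libraries (SD, n = 3 each). Ranked by single locus, next came the muscle-specific miR-206-3p with 5.38% of all counts and the red blood cell miRNA miR-451a with 4.28%. miR-22-3p with 3.01%, miR-378a-3p with 2.19% and miR-143-3p with 1.97% followed, then let-7b-5p, let-7c-5p from both of its loci, and miR-27b-3p. Summing identical copies changes this order. let-7c-5p (average log2 CPM 15.13) then lay above miR-22-3p (14.88). miR-26a-5p (14.34), named after its values were seen, lay above miR-143-3p (14.26). The 10 most abundant loci together held 73.2% ± 0.480 of the counts in young and 71.1% ± 3.88 in old (exact permutation p = 0.6, two-sided).

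Old replicate 1 stood apart from the other libraries. Its share of miR-21a-5p was 35.42% (95% exact binomial interval 35.32 to 35.52), against 48.98% and 52.89% in old replicates 2 and 3 and 49.55% to 51.92% in the young libraries. Its let-7 family, a set of conserved miRNAs that accumulate in differentiated cells, took 15.3% of the counts, against 7.62% to 10.4% in the other 5 libraries, and its muscle-enriched miRNAs took 9.91%, against 4.61% to 6.26%. Its red blood cell miRNAs, at 4.52%, lay close to the 4.03% to 4.5% of the others. Against old replicates 2 and 3 it differed by 199.8 and 313.9 chi-square units per degree of freedom, where these 2 libraries differed by 35.02. Without it, the old and young shares of miR-21a-5p differed by -0.097 percentage points, against -5.27 with it (exact permutation p = 0.6).

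**Figure D1:**
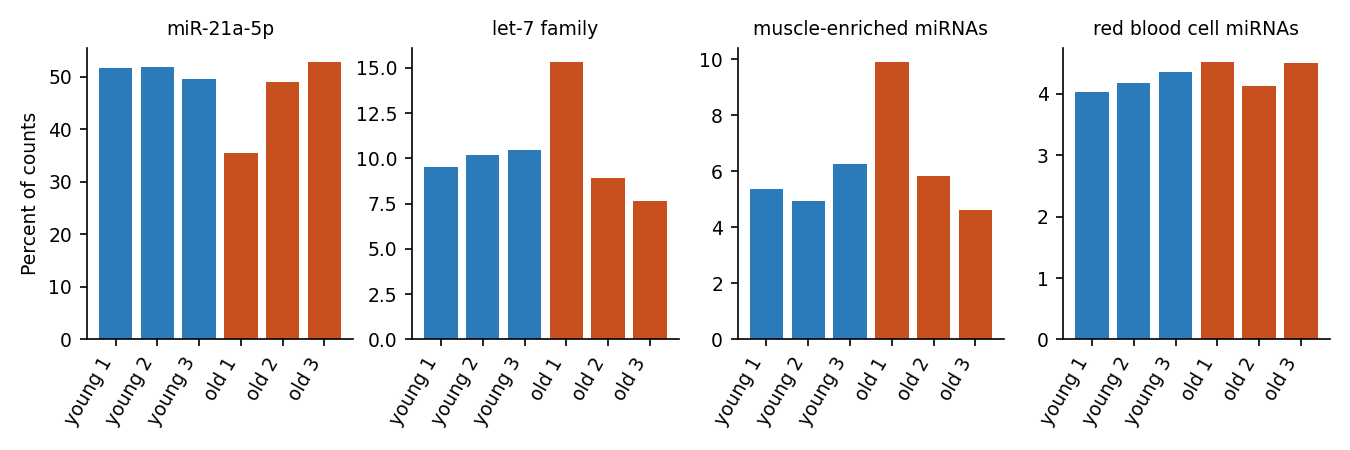
Percent of all counts in each of the 6 libraries taken by miR-21a-5p, the let-7 family, muscle-enriched miRNAs and red blood cell miRNAs (blue, young; orange, old; 1 bar per library, each panel with its own axis from 0). Old replicate 1 holds 35.42% miR-21a-5p and 15.3% let-7 family counts, outside the range of the other 5 libraries, while its red blood cell share of 4.52% is close to theirs.

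Old and young vesicles were compared to ask which miRNAs change in relative amount (TMM-scaled CPM) with the age of the muscle. In these relative units, vesicles from old muscle held about 2-fold more of the striated muscle miRNAs miR-133a-3p and miR-499-5p and 1.64-fold more miR-1a-3p. They also held 2.01-fold more miR-378d and 1.63-fold more of the smooth muscle miRNA miR-143-3p. They held less miR-351-5p, less of the inflammation-associated miR-155-5p and less miR-365-3p (at its locus Mir365-1), at 0.533, 0.571 and 0.508 times the young level. In all, 12 loci (11 mature miRNAs) rose and 3 fell among 347 tested by edgeR's quasi-likelihood test, and all but 1 of these 15 had groups that did not overlap. Over all tested loci the groups did not overlap at 94, or 27.1%, where chance gives 10% for 3 against 3.

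Among the miRNAs enriched in skeletal and heart muscle, miR-133a-3p rose at both of its loci. At Mir133a-2 (MIMAT0000145_1, chromosome 2, 180398437 to 180398458) it went from 1129 ± 82.0 CPM in young to 2442 ± 493 in old, a log2 fold change of 1.11 ± 0.18 (SE, adjusted p = 0.0009), and at Mir133a-1 (chromosome 18, 10782913 to 10782934, in an intron of Mir133a-1hg) by 1.12 ± 0.18. Both loci encode the same mature sequence, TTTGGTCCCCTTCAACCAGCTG, so that they stand for 1 measurement. It differs from miR-133b-3p at 1 of 22 positions, and miR-133b-3p itself, a member of the list, had 588 ± 74.9 and 768 ± 62.0 CPM (log2 fold change 0.39, adjusted p = 0.187). miR-499-5p (MIMAT0003482), which lies in an intron of the slow myosin heavy chain gene Myh7b (chromosome 2, 155622893 to 155622913), went from 767 ± 72.1 to 1532 ± 98.0 CPM (log2 fold change 1.00 ± 0.16, adjusted p = 0.0009). miR-1a-3p at Mir1a-1 (chromosome 2, 180389096 to 180389117) went from 1753 ± 334 to 2876 ± 490 CPM (log2 fold change 0.71 ± 0.18, adjusted p = 0.0285). The most abundant member, miR-206-3p, had 49958 ± 4896 CPM in young and 56330 ± 20624 in old, a log2 fold change of 0.17 ± 0.22 that did not pass (adjusted p = 0.731) and was -0.13 without old replicate 1, the library with the largest muscle-enriched share.

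As a group, the 7 tested muscle-enriched loci, which stand for 6 mature miRNAs, all had positive log2 fold changes with a median of 0.71. Of these 7, 4 rose (both copies of miR-133a-3p among them), both over all tested loci and adjusted over the list alone, none fell and 3 did not pass. The list was called higher in old by camera with the preset correlation (adjusted p = 0.0028), but not with an estimated correlation (adjusted p = 0.443), nor without old replicate 1 (adjusted p = 0.05199, median 0.59). With identical copies summed, so that miR-133a-3p entered once, camera with the preset correlation gave an adjusted p of 0.0219 and the median was 0.54. As a share of all counts it took 5.53% ± 0.667 in young and 6.79% ± 2.78 in old (exact permutation p = 0.7), since miR-206-3p made up most of it. The higher mean share in old rested on old replicate 1 (9.91%), since old replicates 2 and 3 held 5.83% and 4.61%. A further 10 of the 25 loci of this list were listed at 0 in every library, 8 of them loci that overlap another on the opposite strand, among them miR-486a-5p and the second copy of miR-1a-3p at Mir1a-2.

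**Figure D2:**
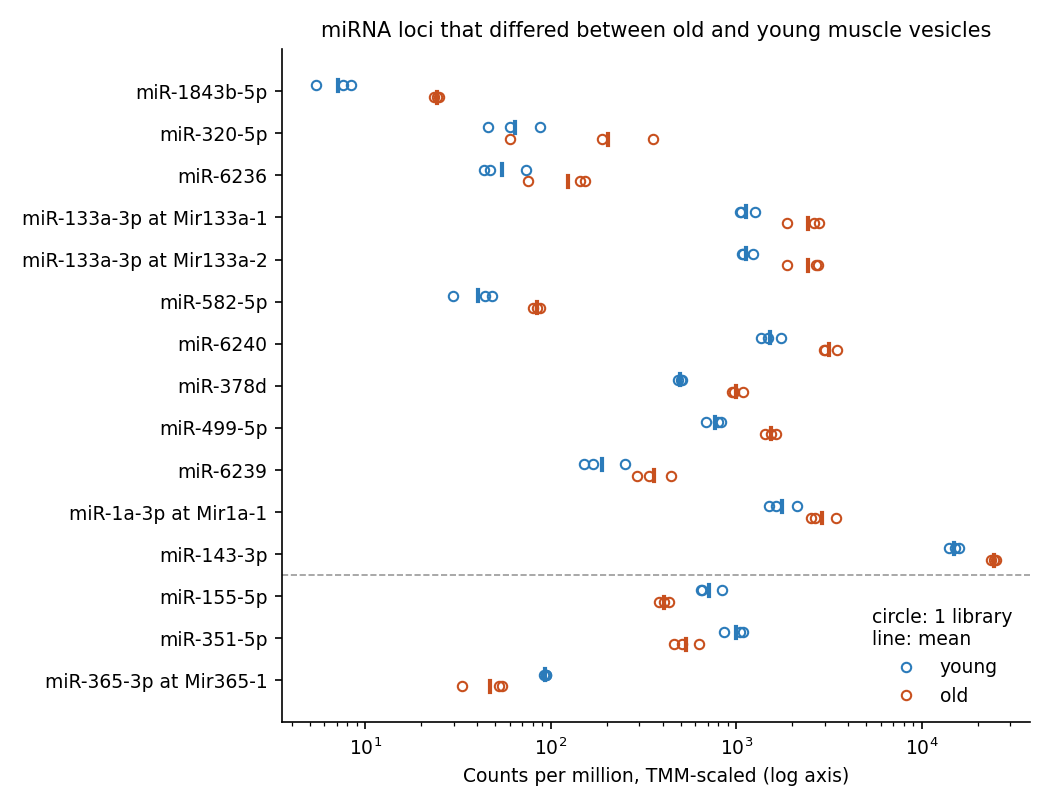
CPM (TMM-scaled, log axis) of the 15 miRNA loci that differed between old and young vesicles, 12 higher in old above the dashed line and 3 lower below it. Circles are single libraries (blue, young; orange, old; 3 each) and vertical strokes are group means; only miR-320-5p has overlapping groups.

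Other miRNAs that rose were not on the muscle list. miR-143-3p (MIMAT0000247, chromosome 18, 61649199 to 61649219), typical of smooth muscle and fibroblasts and the sixth most abundant locus, went from 14953 ± 889 to 24356 ± 767 CPM (log2 fold change 0.70 ± 0.16, adjusted p = 0.0137). miR-378d (MIMAT0025167, chromosome 10, 126710355 to 126710376) went from 498 ± 12.1 to 1000 ± 74.0 CPM (log2 fold change 1.01 ± 0.16, adjusted p = 0.0009). It differs from the far more abundant miR-378a-3p at 1 of the 21 positions compared, and its counts were 2.63% ± 0.14 of those of miR-378a-3p in young and 4.02% ± 0.38 in old (exact permutation p = 0.1). miR-378a-3p, from an intron of the coactivator gene Ppargc1b, had 18955 ± 583 and 24977 ± 2796 CPM and did not pass (log2 fold change 0.40 ± 0.16, adjusted p = 0.155). The less abundant miR-582-5p, in an intron of Pde4d, went from 40.7 ± 9.89 to 83.9 ± 3.90 CPM, and miR-1843b-5p, in an intron of Cop1, from 7.11 ± 1.52 to 24.2 ± 0.888 CPM, a 3.38-fold difference resting on few counts. miR-320-5p, named here after its values were seen, also passed (log2 fold change 1.66 ± 0.42, adjusted p = 0.0280) although the CPM of old replicate 1, 60.5, lay within the young range of 45.7 to 86.9.

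The fixed list of entries that may be fragments of rRNA or tRNA held 3 of the loci that rose. miR-6240 (chromosome 5, 114851973 to 114851998) went from 1526 ± 198 to 3151 ± 288 CPM (log2 fold change 1.05 ± 0.17, adjusted p = 0.0009), miR-6236 (chromosome 9, 110281353 to 110281371) from 54.5 ± 16.1 to 124 ± 42.1 CPM, and miR-6239 (chromosome 14, 117953768 to 117953787, opposite to an intron of Gpc6) from 189 ± 53.0 to 358 ± 78.7 CPM. The fourth tested entry, miR-1983, had a log2 fold change of -0.23 ± 0.19 (adjusted p = 0.538). These 4 entries together took 0.217% ± 0.0295 of the counts in young and 0.398% ± 0.0395 in old (exact permutation p = 0.1), and 3 rose adjusted over the list alone as well. The list had a median of 0.98 and an adjusted p of 0.0561 by camera (0.443 with an estimated correlation). It was called without young replicate 1 (0.0452) or 3 (0.0496) and with copies summed per mature identifier (0.0478).

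Of the 3 miRNAs that fell, miR-351-5p (MIMAT0000609, chromosome X, 53053315 to 53053338), from the cluster that also encodes miR-322 and miR-503, went from 998 ± 121 to 532 ± 85.1 CPM (log2 fold change -0.91 ± 0.18, adjusted p = 0.0060). miR-155-5p (MIMAT0000165, chromosome 16, 84714143 to 84714165), which is made from an exon of its host transcript Mir155hg and is induced in activated immune cells, went from 713 ± 111 to 407 ± 25.9 CPM (log2 fold change -0.81 ± 0.18, adjusted p = 0.0135). miR-365-3p went from 93.0 ± 1.31 to 46.8 ± 11.8 CPM at Mir365-1 (chromosome 16, 13453895 to 13453916; log2 fold change -0.98 ± 0.25, adjusted p = 0.0280). The identical copy at Mir365-2, chosen after its values were seen, had a log2 fold change of -0.75 that did not pass (adjusted p = 0.139). With both copies summed, miR-365-3p passed edgeR's test (log2 fold change -0.89, adjusted p = 0.0399).

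The imprinted Dlk1-Dio3 cluster on chromosome 12, a large miRNA cluster expressed from the maternal allele, was the other list called (adjusted p = 0.0172 by camera with the preset correlation, 0.443 with an estimated correlation and 0.0404 by fry). Of its 14 tested loci, 11 had positive and 3 negative log2 fold changes, with a median of 0.40. No single member passed over all tested loci and 1 passed adjusted over the list alone. Its most abundant members were miR-411-5p, with 371 ± 43.3 CPM in young and 515 ± 19.9 in old (log2 fold change 0.47 ± 0.17, adjusted p = 0.139), and miR-127-3p, with 206.4 ± 12.4 and 308 ± 129 CPM (0.57 ± 0.24, adjusted p = 0.178). The value of miR-127-3p was 0.20 without old replicate 1, and 0.74 without old replicate 3, where it passed (adjusted p = 0.039). The call was also lost without old replicate 1 (adjusted p = 0.05199).

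Lists of other cell types were not called by camera, and fry called 1 of them, the neural list, which camera with an estimated correlation did not (adjusted p = 0.443). Some loci of these lists overlap another and held 0 counts, so that the tests cover only the other loci. These were 13 of 22 neural and 4 of 8 red blood cell loci. Of the liver, leukocyte and epithelial lists they were 2 of 8, 2 of 11 and 2 of 14 loci. Red blood cell miRNAs had 3 tested loci, none past the test, with a median log2 fold change of 0.31 (0.57 without old replicate 1, 0.16 without old replicate 2 and 0.17 without old replicate 3). miR-451a had 41976 ± 1246 CPM in young and 43794 ± 3918 in old (log2 fold change 0.06 ± 0.16), and miR-144-3p had 23.4 ± 1.95 and 28.6 ± 9.89. Of 5 leukocyte loci, miR-155-5p fell and the other 4 had positive values that did not pass, with miR-223-3p at 255 ± 7.0 and 275 ± 37.2 CPM (list adjusted p = 0.657). Of 11 smooth muscle and fibroblast loci, miR-143-3p rose and 10 did not pass, with miR-199a-3p at Mir199a-2 at 0.20 ± 0.16 (list adjusted p = 0.442). This list took 3.87% ± 0.157 of the counts in young and 5.05% ± 0.50 in old (exact permutation p = 0.1). Liver miRNAs had 3 tested loci, for 2 mature miRNAs, with none past the test (list adjusted p = 0.312). Their median of 0.71 was 0.19 without old replicate 1 and 1.07 without young replicate 3. miR-192-5p was at 0.08 and miR-194-5p at Mir194-2 at 0.71 ± 0.35. Neural miRNAs had 4 tested loci, for 2 mature miRNAs, with a median of 0.42 (0.27 without young replicate 2) and none past the test over all loci. The list adjusted p was 0.105 by camera and 0.0404 by fry, and 1 locus passed adjusted over the list alone. These values count miR-124a-3p as 3 identical copies. With copies summed the list had too few members to be tested. The 2 most abundant neural loci were miR-153-3p, at 0.08 ± 0.27, and miR-124a-3p at Mir124a-3. The latter had 16.6 ± 3.56 CPM in young and 32.0 ± 1.69 in old (log2 fold change 0.94 ± 0.32, adjusted p = 0.112 by edgeR). With its identical copies summed, miR-124a-3p had a log2 fold change of 0.58 ± 0.25 (adjusted p = 0.167 by edgeR). Epithelial miRNAs had 1 tested locus, miR-200a-3p, with 4.67 ± 2.19 and 8.34 ± 2.28 CPM, and 145 counts in all libraries together. The 4 endothelial loci, from miR-126a and miR-126b, were all listed at 0, and each of them overlaps another on the opposite strand, so that their amount in the vesicles could not be read from the table.

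**Figure D3:**
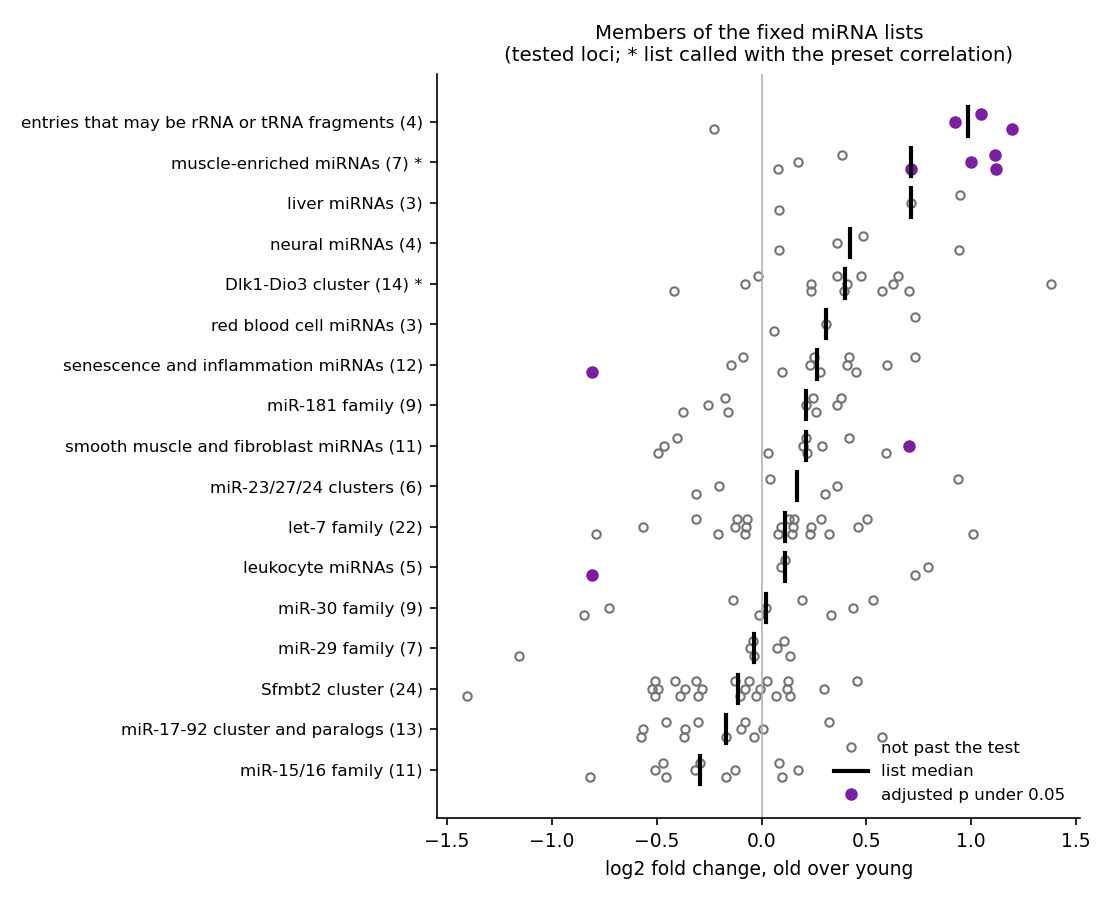
Log2 fold change, old over young, of every tested member of the 17 fixed lists (open circles, not past the test; filled purple, adjusted p under 0.05; black stroke, list median; number of tested loci in parentheses). The muscle-enriched list, with 7 positive loci and a median of 0.71, and the Dlk1-Dio3 cluster, with 11 of 14 positive and a median of 0.40, carry the asterisk of a camera call with the preset correlation.

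Of the miRNAs named in work on senescence and inflammation, 12 loci were tested and 1, miR-155-5p, fell, while 9 had positive values that did not pass. miR-21a-5p had a log2 fold change of -0.15 ± 0.20 (adjusted p = 0.769) and 0.07 without old replicate 1, and miR-22-3p one of 0.28 ± 0.16 (adjusted p = 0.299). The list had a median of 0.26 and was not called by camera (adjusted p = 0.231), while fry gave an adjusted p of 0.0404 and camera with an estimated correlation 0.443.

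No family list was called with all 6 libraries and each locus on its own, and no member of these lists rose or fell over all tested loci. The let-7 family had 22 tested loci with a median of 0.11 (adjusted p = 0.914). Its most abundant members were let-7b-5p at -0.12 ± 0.21 and let-7c-5p at -0.08 ± 0.20 for each of its 2 loci. The miR-30 family had a median of 0.02 over 9 loci (adjusted p = 0.914), with miR-30d-5p at 0.02 ± 0.23 and miR-30a-5p at -0.01 ± 0.21, and 1 member fell adjusted over the list alone. The miR-181 family had a median of 0.21 over 9 loci (adjusted p = 0.914), with miR-181a-5p at 0.36 ± 0.20 and 0.38 ± 0.20 at its 2 loci. The median of this family was 0.031 without young replicate 3 and 0.25 without old replicate 1. The miR-29 family had a median of -0.04 over 7 loci (adjusted p = 0.620), with miR-29a-3p at 0.07 ± 0.16 and miR-29b-3p at Mir29b-2 at -0.06 ± 0.23. The miR-15/16 family, whose members act on cell cycle genes, had 8 of 11 loci below 0, a median of -0.30 and an adjusted p of 0.0627. Of its members, 1 passed adjusted over the list alone. The list was called without old replicate 2 (0.0375) and with copies summed per mature identifier (0.0478). With an estimated correlation it was not called (0.443), and without old replicate 3 its median was -0.17. miR-322-5p had 3684 ± 523 CPM in young and 2587 ± 542 in old (log2 fold change -0.51 ± 0.19, adjusted p = 0.139), and miR-16-5p at Mir16-1 one of -0.13 ± 0.16. The miR-17-92 cluster and its paralogs had 10 of 13 loci below 0 and a median of -0.17 (adjusted p = 0.215), with miR-93-5p at 0.32 ± 0.16 and miR-92a-3p at Mir92-1 at -0.37 ± 0.20. The miRNAs of the Sfmbt2 cluster, in introns of Sfmbt2, had 17 of 24 loci below 0 and a median of -0.11 (adjusted p = 0.206). These 24 loci stand for 12 mature miRNAs, and several of them are copies of miR-467a-5p. With copies summed per mature identifier the median was -0.012 (adjusted p = 0.732 by camera). Without old replicate 2 this list was called (median -0.33, adjusted p = 0.0375), and without old replicate 1 the median was -0.066. With all libraries the list was not called with an estimated correlation (adjusted p = 0.605) or by fry (0.389). Ranked by single locus, its most abundant members were miR-467e-5p at 0.30 ± 0.21 and miR-467c-5p at -0.10 ± 0.34. With copies summed, miR-467a-5p (average log2 CPM 6.99, log2 fold change -0.31 ± 0.26) lay above miR-467e-5p (6.74). The miR-23/27/24 clusters had a median of 0.17 over 6 loci (adjusted p = 0.620), with miR-27b-3p at 0.30 ± 0.17 and miR-27a-3p at 0.36 ± 0.17. The median of these clusters was 0.27 without old replicate 1 and 0.11 without old replicate 2. Their remaining product, miR-24-3p, was listed at 0 in all libraries at both loci.

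**Figure D4:**
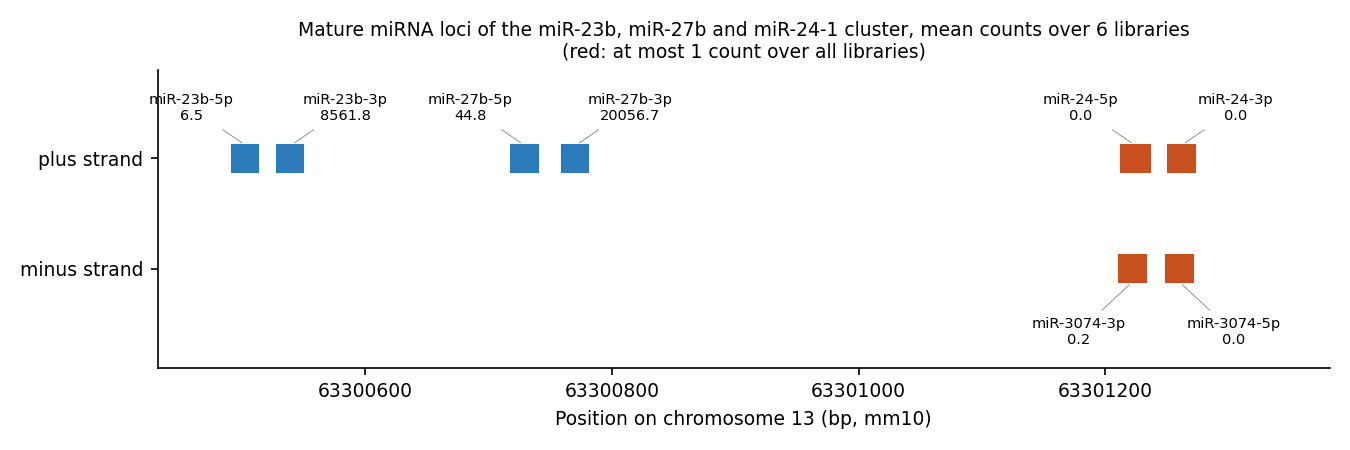
Mature miRNA loci of the miR-23b, miR-27b and miR-24-1 cluster on chromosome 13 (horizontal axis, position in bp, mm10), drawn to scale on their strand, with the mean count over 6 libraries above or below each box. miR-23b-3p and miR-27b-3p hold 8562 and 20057 counts on average, and the 4 loci of miR-24 and miR-3074, which overlap on opposite strands, hold at most 1 count in all.

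The counts of differing loci depended on which libraries were kept. Without young replicate 1, 2 or 3, 5, 5 and 7 loci were higher and 1, 3 and 1 lower; without old replicate 1, 2 or 3, 25, 5 and 17 were higher and 20, 0 and 12 lower, the count of 0 standing beside 23 lower loci at an unadjusted p under 0.05. With upper quartile scaling the split was 11 higher and 6 lower. miR-6240, miR-133a-3p at both loci, miR-378d and miR-499-5p passed without each library in turn, and the other 10 loci lost their call without old replicate 2.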

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

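The summing of identical copies and the removal of possible rRNA or tRNA entries were chosen after seeing the data. The 15 calls kept their direction under all settings in which they were tested, and 15, 14, 11, 15, 14, 14 and 14 of them remained called with RLE scaling, upper quartile scaling, library totals, no low-count filter, at least 50 counts, DESeq2 and limma-voom (with at least 50 counts, 14 were tested). The 12 higher loci numbered 8 to 12 under these settings. The 3 lower loci became 6 with upper quartile scaling, 5 with no low-count filter, 8 with at least 50 counts in every library of 1 group, 9 with DESeq2 and 5 with copies summed per mature identifier. Without the 5 most abundant loci the counts stayed 12 and 3, and without the possible rRNA or tRNA entries they were 9 and 3. The replicate numbers showed no sign of pairing the libraries. Same-numbered young and old libraries had correlations of -0.13, 0.02 and -0.15 of their deviations from the group means. No young library correlated best with its own number. With 3 libraries in each group, these values cannot exclude a batch shared by same-numbered libraries. The fit with the replicate block, which spends degrees of freedom on the numbers, gave 5 higher and 1 lower loci and left the 2 list calls in place. Leaving out 1 library gave 5 to 25 higher and 0 to 20 lower loci. Without young replicate 1, 2 or 3, 6, 7 and 8 of the 15 calls remained, and without old replicate 2 there were 5, where fewer libraries were tested; without old replicate 1 or 3 all 15 remained. For these lower and higher counts the cause was not tested further. The number of lists called, 2, was 0 with an estimated correlation (1 list at an unadjusted p under 0.05), 4 with fry and 4 with copies summed per mature identifier. It ranged from 0 without old replicate 1 (4 lists at an unadjusted p under 0.05, none by fry) to 4 without old replicate 2, which added the Sfmbt2 cluster and the miR-15/16 family. Copies summed added the miR-15/16 family and the possible rRNA or tRNA entries, and fry the neural and the senescence and inflammation lists. The adjusted p of the muscle-enriched list ranged from 0.00072 to 0.443 and that of the Dlk1-Dio3 cluster from 0.00708 to 0.443 over these alternatives. Directions reversed only for values near 0 that were not called with all 6 libraries. The log2 fold change of miR-30d-5p was -0.017 with no low-count filter, -0.018 with at least 50 counts, -0.034 with limma-voom and -0.026 with the replicate block, and that of miR-30a-5p was 0.0048 without the 5 most abundant loci. The median of the miR-30 family was -0.026 with the replicate block, and that of the miR-29 family was 0.0038 with copies summed per mature identifier. Over the libraries left out in turn, log2 fold changes ranged from -0.32 to 0.073 for miR-21a-5p, -0.13 to 0.35 for miR-206-3p, -0.026 to 0.12 for miR-451a, -0.43 to 0.013 for let-7b-5p, -0.36 to 0.058 for let-7c-5p at Mirlet7c-2, -0.37 to 0.055 at Mirlet7c-1, -0.25 to 0.24 for miR-30d-5p, -0.23 to 0.13 for miR-30a-5p, -0.013 to 0.15 for miR-29a-3p, -0.36 to 0.16 for miR-29b-3p at Mir29b-2, -0.43 to 0.23 for miR-467c-5p, -0.013 to 0.20 for miR-223-3p and -0.15 to 0.29 for miR-153-3p. Medians ranged from -0.073 to 0.24 for the miR-30 family, -0.16 to 0.16 for the miR-29 family, -0.13 to 0.17 for the let-7 family, -0.32 to 0.0068 for the miR-17-92 cluster and paralogs and -0.013 to 0.29 for the leukocyte list. The cause of these reversals was not tested. Depth limits the rarer loci: miR-1843b-5p, at 7.11 CPM in young, lies near the 1.76 to 3.32 CPM that a count of 0 allows. The simulation recovered 10 of 24 changes of 1.5-fold, so that at its common dispersion many changes of this size would be missed. The recovery under the real spread between libraries was not tested.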

Other observations

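Genomic clusters and seed families were tested after the data had been seen, as 24 sets of loci that lie within 10 kb of each other or share a seed. No set passed camera with the preset correlation, although 4 had an unadjusted p under 0.05 and fry called 2. A cluster on chromosome X from Mir450b to Mir322 (53048008 to 53054327), which encodes miR-351-5p, had 8 of 11 tested loci below 0. Its median log2 fold change was -0.45 (adjusted p = 0.0839 by camera, 0.4195 with an estimated correlation and 0.00374 by fry). Its members include miR-322-5p at -0.51, miR-503-5p at -0.47 and miR-450b-5p at -0.61, and of the 11 loci only miR-351-5p was called. A second X-linked cluster, from Mir500 to Mir532 (7237695 to 7248477), had 7 of 8 loci below 0, with miR-532-3p at -0.97 and miR-501-3p at -0.73. The median of this cluster was -0.40 (adjusted p = 0.0839 by camera, 0.4195 with an estimated correlation and 0.131 by fry). The cluster of miR-182, miR-96 and miR-183 on chromosome 6 (30165962 to 30169732), miRNAs best known from sensory organs, had all 4 tested loci below 0. Its median was -0.44 (adjusted p = 0.0925 by camera, 0.4195 with an estimated correlation and 0.00374 by fry).

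Within the Dlk1-Dio3 region, the 5 tested loci from Mir409 to Mir410 (chromosome 12, 109743204 to 109743784) all had positive values with a median of 0.41. The adjusted p of this set was 0.0839 by camera, 0.4195 with an estimated correlation and 0.112 by fry. The largest value belonged to miR-410-3p, which went from 9.86 ± 4.47 CPM in young to 26.2 ± 3.62 in old (log2 fold change 1.38 ± 0.40, adjusted p = 0.0545 by edgeR). The p53-responsive miR-34a-5p, abundant in these vesicles, had 8291 ± 1179 CPM in young and 11346 ± 1393 in old and did not pass (log2 fold change 0.45 ± 0.17, adjusted p = 0.139). let-7i-5p, with 9433 ± 1911 and 13349 ± 3990 CPM, had a log2 fold change of 0.50 ± 0.21 (adjusted p = 0.170), and let-7g-5p had 0.46 ± 0.19 (adjusted p = 0.155), whereas let-7b-5p and both let-7c-5p loci lay between -0.12 and -0.08. The let-7 family took 15.3% of the counts in old replicate 1, against 8.93% and 7.62% in old replicates 2 and 3, so that these values may lean on that library. Without old replicate 1, 25 loci were higher and 20 lower. Among those added were miR-30c-5p at Mir30c-2 (log2 fold change -1.10), miR-181a-5p at Mir181a-1 (0.56), miR-27a-3p (0.52), miR-378a-3p (0.51), miR-92a-3p at Mir92-1 (-0.65) and let-7b-5p (-0.43).

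For the patterns weighed here, the tests of overlapping loci, of the scaling, of GC content and of equal change were chosen after the result was seen; the splits and the test of old replicate 1 were set before. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 12 higher and 3 lower loci and each of the other splits gave 0 in either direction, so that 1 split of 10 reached either count. For the lists, 2 of the 10 splits called at least as many as the real one: it called 2, and the highest of the others, which exchanged young replicate 3 with old replicate 2, called 3. Further mixed splits called 1 list each, among them the one that exchanged young replicate 3 with old replicate 3. List calls at the preset correlation thus also arose between groups that mix the ages.

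Loci that overlap another on the opposite strand were empty even for miRNAs whose neighbours were abundant: miR-24-3p was listed at 0 at both loci, beside mean counts of 8562 for miR-23b-3p and 20057 for miR-27b-3p from the same cluster. Absence from the vesicles is argued against for miR-1a-3p, whose copy at Mir1a-2, under an overlap, held 0 counts while the identical copy at Mir1a-1 held at least 2359 in every library. This was the only identical copy outside an overlap with over 100 counts in every library. Whether the other overlapping miRNAs were present was therefore not tested. Loss of reads over 2 features during counting predicts empty loci throughout, and 98.1% of the 106 overlapping loci were at 0 in all libraries, against 50.4% of the other 2004. A likely consequence is that miR-24, miR-126a, miR-486a, miR-142a-3p and miR-122-5p cannot be read from this table at any depth, and whether they differ with age stays open.

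The rise of miR-133a-3p, miR-499-5p and miR-1a-3p was weighed against the scaling, the base composition and the amount of muscle RNA. Under 3 other scalings the median log2 fold change of the 4 loci was at least 1.03, against 1.06 with TMM. miR-1a-3p lost its call under upper quartile scaling and library totals. The list median, with TMM the value of miR-1a-3p, was 0.73 with library totals against 0.71 with TMM. Under every scaling the median of all tested loci lay between 0.007 and 0.038, so that changing the scaling could move the 4 loci little. None of the scalings can show a shift of all miRNAs at once. Log2 fold changes hardly followed GC content over the 347 loci (slope 0.022 per 10 points, r = 0.05), and loci outside the list within 5 GC points of each of the 4 had medians of at most 0.105. More RNA from all muscle cells alike would change the muscle miRNAs by 1 common factor, yet the 6 tested mature miRNAs of the list, called or not and with copies summed, differed in their change: Cochran's Q was 19.5 on 5 degrees of freedom (upper 5% point 11.1), and at least 12.5 without any 1 library, taking miRNAs as independent and their SE as known, with 0.16 ± 0.21 (SE) for miR-206-3p and 1.1 ± 0.18 for miR-133a-3p. Of the 4 entries that may be rRNA or tRNA fragments, 3 were called higher as well, with their list near the threshold (adjusted p = 0.0561, and 0.0452 to 0.158 without 1 library), and so was miR-143-3p of the smooth muscle and fibroblast list, so that a difference in RNA quality, in source tissue or in the vesicle preparation stays open. The age of the mice, which the design names, stays open as well and was not tested against these.

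Old replicate 1 stood apart with its low share of miR-21a-5p. A loss of miR-21a-5p alone would leave the rest of the library like the others, yet without miR-21a-5p it still differed from old replicates 2 and 3 by 77.6 and 115 chi-square units per degree of freedom, where these 2 differed by 22.8. A different mix of source cells or a different preparation of this library could each give such a difference, and with 1 library no test can part them. No biological explanation was tested.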
